A study of Homo sapiens with 8 samples.

How the data were processed

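Total RNA from THP-1 cells, a human acute monocytic leukaemia line that carries an MLL-AF9 fusion, was hybridised to 1-colour Affymetrix whole-transcript expression arrays after biotin labelling, per the labels. Cells had been treated for 5 h with IPA-3 at 6 µg/mL, with FRAX-597 at 2 µg/mL, or with an equal volume of the solvent DMSO. The 8 arrays comprised 4 of DMSO, 2 of IPA-3 and 2 of FRAX-597. The submitters' processing notes name Affymetrix Expression Console and Transcriptome Analysis Console, without versions. The summarisation and normalization method behind the values is not given in the sources used here.

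The deposited table holds log2 expression values for 53617 probes in 8 arrays, with no missing values. It is the authors' processed table, and its scale and the arrays normalized together are not stated. The median over all probes lay between 5.51 and 5.55 in DMSO 1, DMSO 2, IPA-3 1 and IPA-3 2, and between 6.00 and 6.05 in DMSO 3, DMSO 4, FRAX-597 1 and FRAX-597 2. These groups of 4 arrays are called the first and the second array set below. They were recognised from the distribution and correlation of the values and carry no label. Arrays have no read depth, so the number of arrays limits the precision.

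The platform annotation paired 16098 probes with exactly 1 gene and 0 with several, and 37519 probes carried no gene name here. All 16098 gene identifiers and symbols matched the gene reference for GRCh38.p14, which was used for names only. The array design's genome build is not given in the sources used here, so no coordinates are given. For 779 genes with more than 1 probe, the probe with the highest mean over the 8 arrays was kept, which left 14884 genes. PAK1, PAK3 and PAK6 were not among the named probes and are not analysed here.

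The test fixed before the data were examined was limma (version 3.58.1, R 4.3.3; lmFit and eBayes) on the log2 values, with one fit of 3 groups over all 8 arrays, no covariate, and a Benjamini-Hochberg adjusted p under 0.05. This is called the pooled-control fit. Among the alternatives fixed in advance, each compound was set against DMSO 1 and 2 only or against DMSO 3 and 4 only, in a fit with the DMSO pairs as separate groups. IPA-3 against DMSO 1 and 2 and FRAX-597 against DMSO 3 and 4 compare arrays of the same set, and this is called the within-set fit. It was chosen to carry the gene-level description after the 2 sets were seen to lie on different scales. The difference between the compounds in that fit is the difference of the 2 within-set changes, an alternative added after the data were examined.

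No replicate numbers in the labels are shared by the compounds and DMSO, so no pairing was planned. In the second set, however, the difference DMSO 3 minus DMSO 4 correlated with FRAX-597 1 minus FRAX-597 2 at r = 0.65 across 14884 genes, which are not independent replicates, whereas the corresponding value in the first set was -0.06. A fit with DMSO 3 and FRAX-597 1, DMSO 4 and FRAX-597 2, and the first set as blocks was therefore added after the data were examined and is called the pair-block fit. Its pairs were chosen from these same values, which favoured a smaller spread and more calls. The gain in calls is therefore no separate support. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these arrays, which may be technical.

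Before the data were examined, 32 gene lists with 858 genes were fixed from general knowledge. They covered MYC targets, ribosome synthesis, stress responses, sterol metabolism, signalling outputs, cell cycle, inflammation, myeloid and leukaemia genes, metabolism, and markers of other cell types. Of these genes 526 were measured, and 30 lists had at least 5 measured genes. The erythroid markers with 4 measured genes and the fibroblast markers with 3 were not tested. Lists were tested with camera from limma, which compares a list with all other genes, at a preset inter-gene correlation of 0.01. Adjustment was over the lists of a contrast. Camera with an estimated correlation and fry were run beside it. Members were also counted with adjustment over the list alone.

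The rule for named genes, fixed in advance, took MYC and PAK1 to PAK6; the 8 largest rises and falls per compound at an adjusted p under 0.05 with every compound array on one side of every DMSO array, leaving out unnamed transcripts, small RNAs and pseudogenes; up to 3 members per called list with the smallest adjusted p; 3 MYC targets with the largest change; and the 6 largest differences each way between the compounds. The same rule was repeated on the within-set fit, where each compound was set against the DMSO arrays of its own set. Of the genes this gave, the text names some of those of the within-set fit, and for several lists not all members that the rule took.

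The procedure was tested on simulated data with 200 of 14884 genes changed. Each gene had the same spread in both array sets, and values were drawn independently. The recovery below holds for that setting, which leaves out the pairing of the second set and any difference in spread between the sets. At a log2 change of 1, the pooled-control fit recovered 21.7% of changed genes for IPA-3 and 22.0% for FRAX-597. The within-set fit recovered 65.4% and 67.6%. At a log2 change of 2, it recovered 94.6% and 95.4%, and the pooled-control fit 75.2% and 76.3%. False calls per draw numbered 8.2 for IPA-3 and 7.1 for FRAX-597 in the within-set fit, against 1.5 and 1.1 in the pooled-control fit. Simulated lists of 25 genes shifted by 0.5 were called by camera in 10 of 10 draws for FRAX-597 in the second set, and unshifted lists in 0 of 10. These list calls used an unadjusted camera p under 0.05. The simulated genes varied independently of each other. The result therefore cannot show how often camera at the preset correlation calls unshifted lists of correlated genes.

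The alternatives were leaving out the dimmest 4961 genes, every probe as its own feature, quantile normalization, median centring, an intensity trend or robust spread in eBayes, only the groups compared in the fit, a minimum log2 change of 1, and leaving out each array in turn. For lists and named genes, the mean over a gene's probes took the place of separate probes. Every probe was also tested without regard to its name. The within-set fit then called 4 of the 37519 unnamed probes for FRAX-597 and 0 for IPA-3.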

Results

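THP-1 is a human acute monocytic leukaemia line that carries an MLL-AF9 fusion. Gene expression was measured in these cells after 5 h with either of 2 inhibitors of the p21-activated kinases (PAKs), or with the solvent DMSO. IPA-3, used at 6 µg/mL, is an allosteric inhibitor that does not compete with ATP. FRAX-597, used at 2 µg/mL, is an ATP-competitive inhibitor of group I PAKs. The study asked about PAK1 as a drug target in acute myeloid leukaemia and myelodysplastic syndrome, and about the expression of MYC. There were 4 DMSO arrays, 2 IPA-3 arrays and 2 FRAX-597 arrays, each giving log2 values for 14884 named genes. The number of arrays limits the precision, and the labels do not say whether replicates came from separate cultures.

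The 8 arrays fell into 2 sets of 4. DMSO 1, DMSO 2 and both IPA-3 arrays formed the first set, with medians over all probes from 5.51 to 5.55. DMSO 3, DMSO 4 and both FRAX-597 arrays formed the second set, with medians from 6.00 to 6.05. Correlations over all probes ran from 0.986 to 0.992 within the first set, from 0.974 to 0.990 within the second, and from 0.942 to 0.956 between sets. DMSO 3 and 4 against DMSO 1 and 2 gave 8918 of 14884 genes at an adjusted p under 0.05 in limma, with a median shift of 0.48. Each of the other 2 ways of pairing the DMSO arrays gave 0 genes in limma, with 11 and 10 at an unadjusted p under 0.05. By construction, each side of these pairings held 1 array of each set, so the shift widened the spread within a side. A count far under the 744.2 expected by chance was therefore fixed in advance. Against that shift, ribosome-synthesis and unfolded protein response genes ranked lower in DMSO 3 and 4. Relative to all genes, the median of the RNA polymerase I and rRNA processing list was -0.47 (camera adjusted p = 1.27e-05, and adjusted p = 0.717 with an estimated correlation). The unfolded protein response list had a median of -0.54 (camera adjusted p = 0.00119, and adjusted p = 0.609 with an estimated correlation). Each compound therefore had its own pair of DMSO arrays on its own scale, and the changes below are within-set changes, 2 arrays against 2, unless the pooled controls are named.

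**Figure D1:**
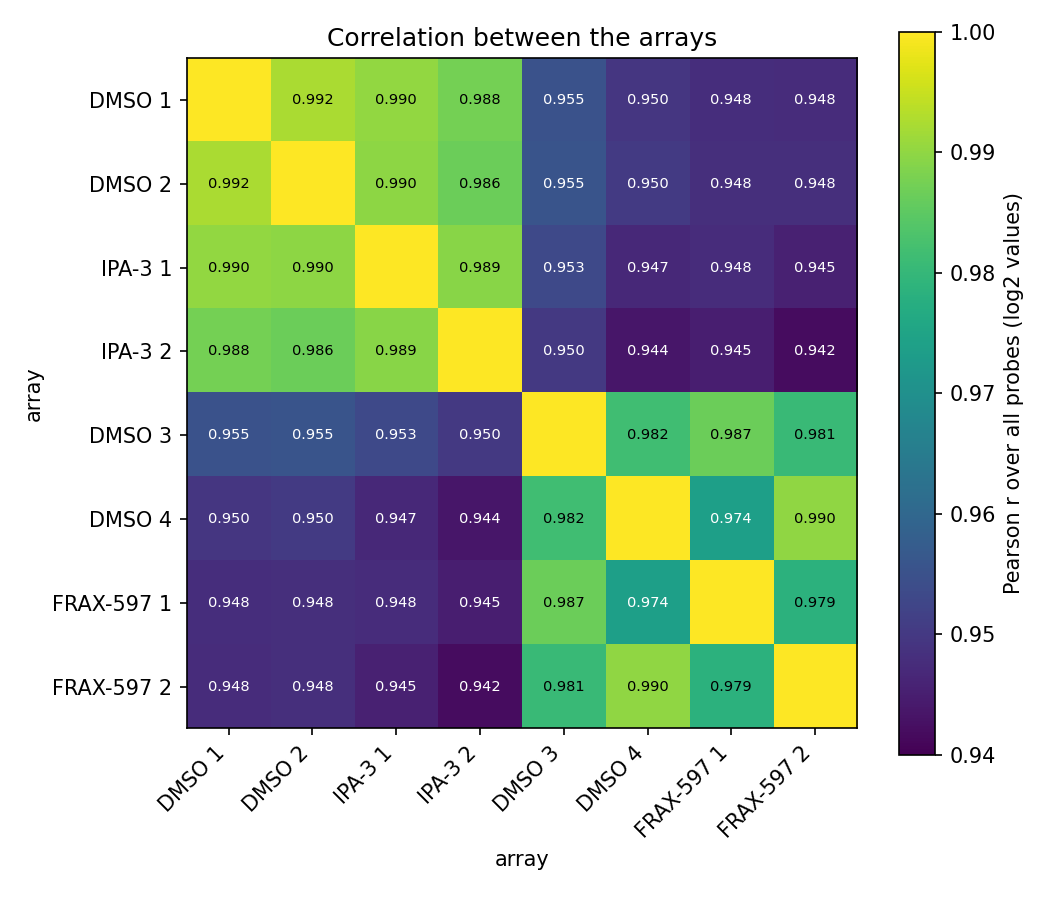
Pearson correlation of log2 values over all probes for each pair of the 8 arrays, with arrays on both axes and colour from 0.94 to 1. Correlations between the 2 sets lie at or below 0.956, under every correlation within a set (0.974 or more).

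The first comparison asked what 5 h of IPA-3 changed. SRXN1 (sulfiredoxin, which reduces hyperoxidised peroxiredoxins; probe 16916352) and OSGIN1 (an oxidative stress-induced growth inhibitor; probe 16821414), both targets of the antioxidant factor NRF2, rose. SRXN1 went from 7.77 ± 0.13 (SD, n = 2) in DMSO to 9.71 ± 0.16 (SD, n = 2), a 3.84-fold rise (log2 change 1.94, SE 0.14; limma adjusted p = 0.0108). OSGIN1 rose 3.29-fold (log2 change 1.72, SE 0.12; adjusted p = 0.0108). The DMSO arrays of the second set had higher levels of both genes than those of the first, at 8.85 for SRXN1 against 7.77 and 7.04 for OSGIN1 against 6.17. These differences include the median shift of 0.48 over all genes. Relative to all genes they were 0.60 for SRXN1 and 0.39 for OSGIN1. NRCAM, a neuronal cell adhesion molecule, rose by a log2 change of 1.40 (SE 0.13; adjusted p = 0.038). Its level in DMSO was 3.90, under the lower quartile of all probes in DMSO 1 (4.15) and DMSO 2 (4.14) and not shown to be above background, so the size of its rise is uncertain. CYSLTR1, a receptor for cysteinyl leukotrienes, fell by 1.41 on the log2 scale (SE 0.14; adjusted p = 0.043).

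The 5 genes called for IPA-3, 4 higher and 1 lower, also included C1orf21, named after its values were seen (log2 change 1.63, SE 0.16; adjusted p = 0.038). An unadjusted p under 0.05 was found for 1073 genes, against 744.2 expected by chance. With the 4 DMSO arrays pooled, as fixed in advance, limma called 0 genes for IPA-3, with 843 at an unadjusted p under 0.05 and a median over all genes of -0.26. With the pairs of the second set as a block the count was 72 (55 higher, 17 lower), and with the 4 arrays of the first set fitted alone it was 96 (77 higher, 19 lower). The within-set count was 0 without DMSO 1, DMSO 2, IPA-3 1 or IPA-3 2 (491 to 1146 at an unadjusted p under 0.05), 2 without DMSO 3 or DMSO 4, and 24 without FRAX-597 1 or FRAX-597 2. It was also 0 when every probe was tested as its own feature (3416 at an unadjusted p under 0.05).

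As a group, the 15 measured NRF2 targets had a median log2 change of 0.42, with 13 above 0 (camera adjusted p = 1.23e-12, and adjusted p = 0.328 with an estimated correlation). Of these, 2 rose with adjustment over all genes and 8 when adjusted over the list alone. TXNRD1, thioredoxin reductase, had a log2 change of 0.96 (SE 0.14; adjusted p = 0.18). The heat shock list also ranked higher, with 10 of 13 members above 0 and a median of 0.11 (camera adjusted p = 0.00161, and adjusted p = 0.486 with an estimated correlation). HSPA6, a strictly inducible HSP70, was its 1 member called when adjusted over the list alone, with 0 over all genes, and had a log2 change of 1.49 (SE 0.26). BAG3, a cochaperone of HSP70, had a change of 0.51 and HSPA1A of 0.69, neither called. In the fit with pooled controls, the NRF2 list (adjusted p = 0.0332) and the heat shock list (adjusted p = 0.0375) were called with an estimated correlation too, but that fit ignores the array sets. It adds DMSO 3 and 4, where the 2 lists had medians of -0.24 and -0.45 relative to all genes, to the controls of IPA-3, and so is no separate support.

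Sterol and proliferation genes lay lower with IPA-3, by small amounts. All 18 cholesterol synthesis genes were below 0, with a median of -0.25 (camera adjusted p = 0.00142, and adjusted p = 0.486 with an estimated correlation), which was -0.16 without IPA-3 2. The called members numbered 0 over all genes and 0 when adjusted over the list alone, with 1 at an unadjusted p under 0.05. MSMO1, a sterol methyl oxidase, had a change of -0.45 (SE 0.20). MYC targets had a median of -0.15, with 28 of 37 below 0 (camera adjusted p = 0.00161, and adjusted p = 0.486 with an estimated correlation). Of these, 0 were called over all genes or adjusted over the list alone, and 5 were lower and 1 higher at an unadjusted p under 0.05. The uracil-DNA glycosylase gene UNG had the largest change among them, -0.58 (SE 0.13; adjusted p = 0.454). Of 28 mitotic genes 25 were below 0 and 0 were called over all genes or adjusted over the list alone, with a median of -0.14 (camera adjusted p = 0.00275, and adjusted p = 0.549 with an estimated correlation). The 10 unfolded protein response genes were all below 0 (median -0.17; camera adjusted p = 0.00297, and adjusted p = 0.328 with an estimated correlation), with 0 members called over all genes and 1, MANF, when adjusted over the list alone (-0.56, SE 0.10). With pooled controls the calls of all 4 of these lists ended (camera adjusted p 0.126, 0.321, 0.473 and 0.926 in the order MYC targets, cholesterol, mitosis, unfolded protein response). The unfolded protein response list then ranked higher among all genes, with its median still below 0 at -0.24. Quantile normalization ended the call of the mitotic genes (median -0.07, 0.123) and left medians of -0.10 for MYC targets and -0.09 for the unfolded protein response.

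NF-kB and inflammatory genes ranked higher with IPA-3, with 16 of 18 above 0 and a median of 0.59 (camera adjusted p = 0.00161, and adjusted p = 0.634 with an estimated correlation), with 0 members called over all genes, 0 when adjusted over the list alone, and 0 at an unadjusted p under 0.05. These counts use a spread shared with the second set, whose 2 pairs of arrays differed in these genes by a median of -1.12. With that pairing as a block, 0 were called over all genes, 1 was higher when adjusted over the list alone and 7 at an unadjusted p under 0.05. In the first set fitted alone, RELB, a subunit of NF-kB, (log2 change 0.73, adjusted p = 0.0406) and CCL20 (adjusted p = 0.0497) passed. CCL20, a chemokine, had a change of 0.87 (SE 0.38) from a DMSO level of 3.76, under the lower quartile of all probes. Another 5 lists were called with weaker support, each losing its call when an array was left out and each with 0 members called over all genes or adjusted over the list alone. The ATF4 and integrated stress response list lay higher (median 0.20, camera adjusted p = 0.0114; 0.0519 without DMSO 1, and 0.184 with a median of 0.09 without IPA-3 1, and adjusted p = 0.647 with an estimated correlation). LXR targets (median -0.22, camera adjusted p = 0.00622; 0.0605 without IPA-3 2, and adjusted p = 0.328 with an estimated correlation) lay lower. So did the G1 to S and DNA replication list (median -0.13, camera adjusted p = 0.00353; 0.0518 without IPA-3 2, and adjusted p = 0.597 with an estimated correlation). The RNA polymerase I and rRNA processing list was also lower (median -0.15, camera adjusted p = 0.00713; 0.101 with a median of -0.10 without IPA-3 2, and adjusted p = 0.585 with an estimated correlation), as was oxidative phosphorylation (median -0.16, camera adjusted p = 0.0146; 0.0611 without DMSO 2, and 0.0926 with a median of -0.09 without IPA-3 2, and adjusted p = 0.518 with an estimated correlation). The 4 lower ones of these 5 also lost the call with pooled controls (0.303 to 0.864), where the RNA polymerase I list ranked higher among all genes (median -0.09). Quantile normalization ended the calls of RNA polymerase I and rRNA processing (median -0.0741, 0.237), G1 to S and DNA replication (-0.0705, 0.0676) and oxidative phosphorylation (-0.0945, 0.0819).

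In total 12 of 30 lists were called, 4 higher and 8 lower. The other 18 had camera adjusted p from 0.149 to 0.962. They were ribosomal proteins, metallothioneins, ERK pathway output, immediate early genes, SRF and actin cytoskeleton, PAK family and partners, p53 targets, BCL2 family, interferon response, monocyte and macrophage genes, MLL-fusion and leukaemia progenitor genes, WNT targets, FOXO targets, hypoxia and glycolysis, lysosome and autophagy, and the T cell, B cell and epithelial markers. Median and test differed in sign for FOXO targets (median 0.03, ranked lower) and for lysosome and autophagy (median -0.03, ranked higher).

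The next comparison asked what 5 h of FRAX-597 changed. THBS1, which encodes the secreted glycoprotein thrombospondin-1 (probe 16799315), rose 29.8-fold, from 6.28 ± 0.26 to 11.18 ± 0.45 (SD, n = 2 each; log2 change 4.89, SE 0.22; limma adjusted p = 0.000595). SYT4, a synaptotagmin of membrane trafficking, rose by a log2 change of 2.59 (SE 0.14; adjusted p = 0.00102). Its DMSO level of 4.83 lay near the lower quartile of all probes in DMSO 3 (4.64) and DMSO 4 (4.73) and is not shown to be above background, so the size of its rise is uncertain. STAT4, a transcription factor downstream of interleukin-12, rose by a log2 change of 3.42 (SE 0.35), CRLF2, a subunit of the TSLP receptor, by 2.83 (SE 0.26), and IL7R, the interleukin-7 receptor alpha chain, by 2.10 (SE 0.25). DDIT4 (REDD1, a stress-induced inhibitor of mTORC1) rose by 2.12 (SE 0.25), the angiogenic factor VEGFA by 2.05 (SE 0.24), the T-box factor TBX15 by 2.08 (SE 0.20) and F2RL3, the thrombin receptor PAR4, by 2.05 (SE 0.23). Adjusted p for these genes lay between 0.0254 and 0.032.

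MYB and 4 other genes fell. MYB, a transcription factor that MLL-rearranged leukaemia cells depend on, fell by 0.93 on the log2 scale (SE 0.11; adjusted p = 0.029). URB2, a ribosome biogenesis factor, fell by 1.07 (SE 0.13; adjusted p = 0.0381). NOP16, a nucleolar protein and MYC target, fell by 0.98 (SE 0.11; adjusted p = 0.029). RXFP1, a relaxin receptor, fell by 1.02 (SE 0.11; adjusted p = 0.029) and MYOZ1, a Z-disc protein of muscle, by 0.92 (SE 0.10; adjusted p = 0.029).

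In all 23 genes were called for FRAX-597, 18 higher and 5 lower, with 1140 at an unadjusted p under 0.05. With pooled controls limma called 5, all higher, namely THBS1, CRLF2, SYT4, DDIT4 and IL7R, and all 5 were among the 23. The pair block raised the count to 202 (143 higher, 59 lower), and all 23 were among them. Its pairs were chosen from these same values, so neither the gain nor the retained 23 is separate support. Quantile normalization with pooled controls gave 26 (23 higher, 3 lower). The 4 arrays of the second set fitted alone gave 0 in limma, with 606 at an unadjusted p under 0.05, under the 744.2 expected by chance. The within-set fit takes 1 spread per gene from both sets. The DMSO arrays correlated at 0.992 in the first set and at 0.982 in the second. The SE and adjusted p given for FRAX-597 therefore rest in part on the arrays of the first set. Testing every probe as its own feature gave 6 probes, of which 4 carried no gene name. THBS1 and SYT4 passed whichever array was left out (highest adjusted p 0.0146 and 0.0168). The count was 2 without DMSO 1, DMSO 2, IPA-3 1 or IPA-3 2, 5 without DMSO 3, 7 without DMSO 4 and 227 without FRAX-597 2.

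**Figure D2:**
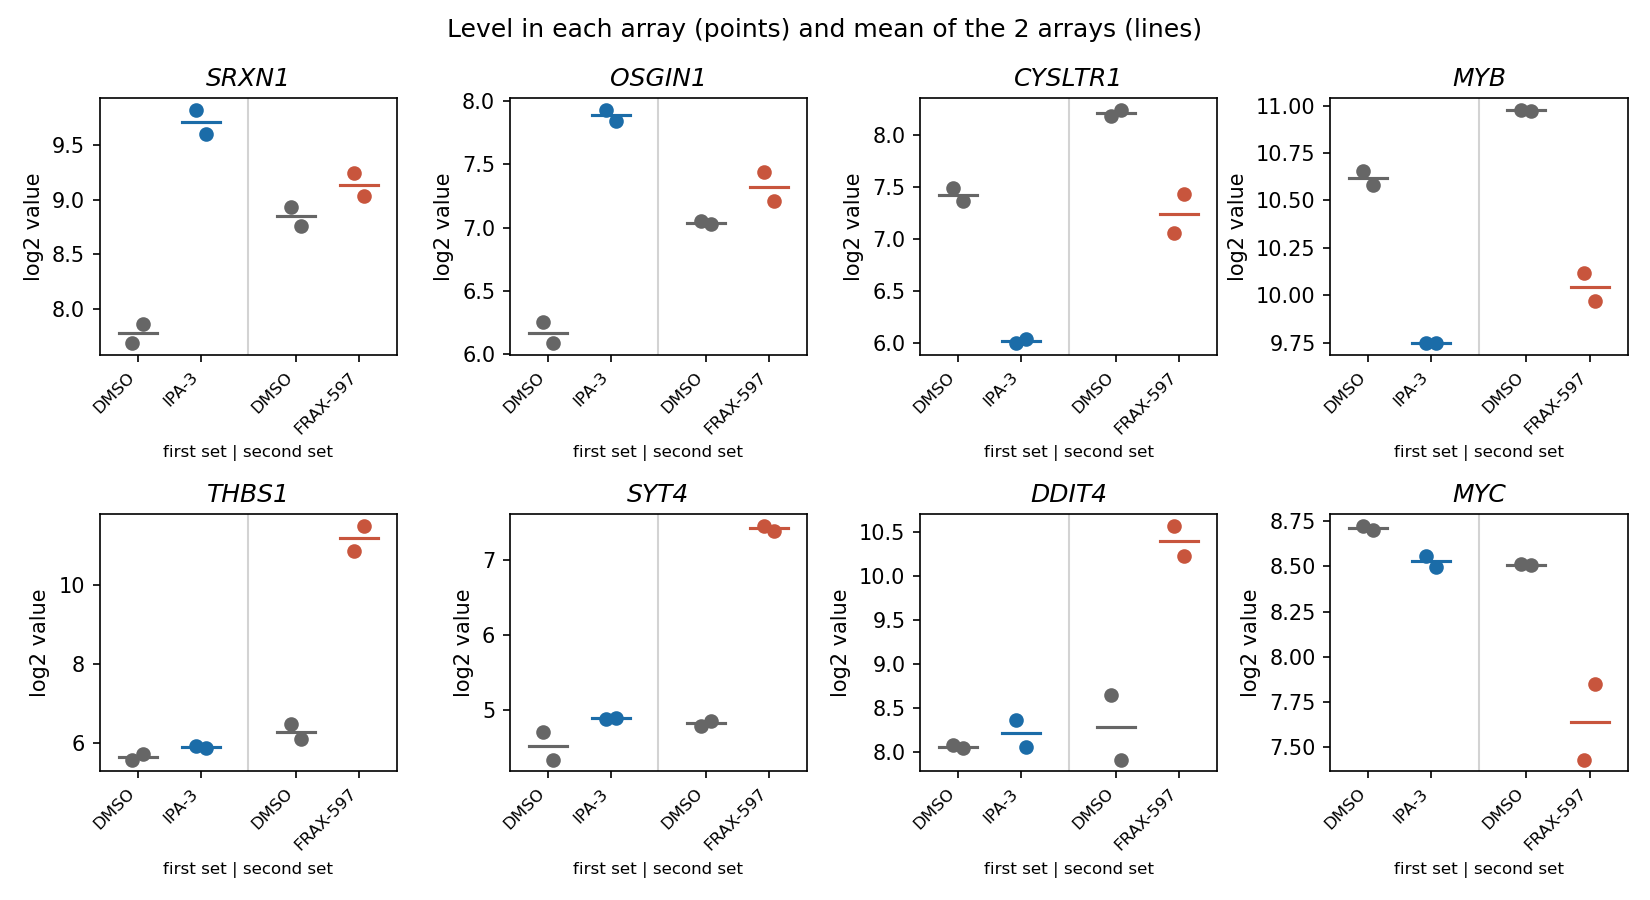
Log2 value of 8 genes in each array (points) and the mean of the 2 arrays (lines), with the first array set left and the second set right of the grey line. SRXN1 and OSGIN1 are higher in both IPA-3 arrays, THBS1, SYT4 and DDIT4 in both FRAX-597 arrays, and MYB is lower in both arrays of each compound than in the DMSO arrays of its set. The vertical axes do not start at 0.

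Genes of the ATF4 and integrated stress response and of cholesterol synthesis ranked higher with FRAX-597. Of 25 measured genes of the ATF4 list, 24 lay above 0, with a median log2 change of 0.82 (camera adjusted p = 1.03e-28, and adjusted p = 0.191 with an estimated correlation). The count of risen members was 2 over all genes and 17 when adjusted over the list alone. DDIT4 and VEGFA were the 2 called over all genes, and AARS1, the alanyl-tRNA synthetase, had a change of 0.85 (SE 0.12; adjusted p = 0.0573). Cholesterol synthesis genes also lay higher, 16 of 18 above 0 with a median of 0.45 (camera adjusted p = 4.95e-12, and adjusted p = 0.191 with an estimated correlation). Of these, 0 rose over all genes, 9 when adjusted over the list alone, and 12 had an unadjusted p under 0.05. These counts leave out the pairing of the second set, whereas the pair-block fit called 202 genes for FRAX-597 over all genes. MSMO1, INSIG1 and MVK each gained a call over all genes in 1 of 17 alternatives. MSMO1 had a change of 1.14 (SE 0.20), INSIG1, an endoplasmic reticulum protein that holds back SREBP, of 1.11 (SE 0.21), and mevalonate kinase MVK of 0.59 (SE 0.12).

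MYC targets and ribosome-synthesis genes lay lower with FRAX-597. Of 37 MYC targets 36 were below 0, with a median of -0.27 (camera adjusted p = 3.3e-14, and adjusted p = 0.191 with an estimated correlation). NOP16 was the 1 that fell over all genes, and 5 fell when adjusted over the list alone. RCL1 had a change of -0.64 (SE 0.10, limma adjusted p = 0.0876) and NIP7 of -0.61 (SE 0.11, limma adjusted p = 0.151), both factors of ribosome assembly. RCL1 and NIP7 each gained a call over all genes in 1 of 17 alternatives. Of 28 genes of RNA polymerase I and rRNA processing 27 were below 0, with a median of -0.28 (camera adjusted p = 9.03e-10, and adjusted p = 0.327 with an estimated correlation), which was -0.13 without FRAX-597 2. The falls counted 0 over all genes and 6 when adjusted over the list alone, with 11 at an unadjusted p under 0.05. RRS1 and PNO1, both needed for ribosome assembly, had changes of -0.80 (SE 0.12) and -0.59 (SE 0.13). The G1 to S and DNA replication list had 26 of 27 members below 0 and a median of -0.31 (camera adjusted p = 9.4e-10, and adjusted p = 0.385 with an estimated correlation; median -0.19 without FRAX-597 1), with 0 called over all genes or adjusted over the list alone and 10 lower at an unadjusted p under 0.05. CDC25A, a phosphatase that activates CDK2, had a change of -0.78 (SE 0.21), which was -0.46 without FRAX-597 1 and -1.10 without FRAX-597 2. Heat shock genes lay lower in 12 of 13 cases, with a median of -0.28 (camera adjusted p = 2.78e-05, and adjusted p = 0.305 with an estimated correlation, and median -0.16 without DMSO 3), 0 called over all genes, 3 adjusted over the list alone and 5 at an unadjusted p under 0.05. HSPA1A and HSPA1B, which are near-identical copies that probes may not separate, both had a change of -0.85, which was -0.43 for both without FRAX-597 1, and -1.27 and -1.28 without FRAX-597 2.

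Another 4 lists were called higher with FRAX-597, each depending on single arrays and each with 0 members called over all genes. Adjusted over the list alone, 2 immediate early genes were higher and 1 lower, 2 FOXO targets were higher, and 0 genes of the other lists were called. NF-kB and inflammatory genes had a median of 0.82 (camera adjusted p = 1.08e-05, and adjusted p = 0.636 with an estimated correlation), which was -0.04 without FRAX-597 1. Immediate early genes had a median of 0.43 (camera adjusted p = 0.000154, and adjusted p = 0.598 with an estimated correlation), and lost the call without DMSO 4 (median 0.21, 0.108) or FRAX-597 1 (median -0.03, 0.971). FOXO targets (median 0.14, camera adjusted p = 0.0334, and adjusted p = 0.429 with an estimated correlation) lost it without IPA-3 1 or IPA-3 2 (0.0534 each), DMSO 4 (0.143) or FRAX-597 1 (median 0.06, 0.315). The lysosome and autophagy list (median 0.13, camera adjusted p = 0.0488, and adjusted p = 0.853 with an estimated correlation) kept it without DMSO 3 or FRAX-597 2 only and turned to -0.04 without FRAX-597 1 and to -0.0096 without DMSO 4. FOXO targets (0.471) and the lysosome list (0.238) also lost the call with pooled controls. The other 20 of the 30 lists had camera adjusted p from 0.114 to 0.979, among them NRF2 targets (median 0.01, adjusted p = 0.424), PAK family and partners (0.02, 0.979), ribosomal proteins (-0.04, 0.432), MLL-fusion and leukaemia progenitor genes (-0.05, 0.114) and the T cell, B cell and epithelial markers. Median and test differed in sign for the PAK list (ranked lower) and for T cell and B cell markers (medians -0.03, ranked higher).

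**Figure D3:**
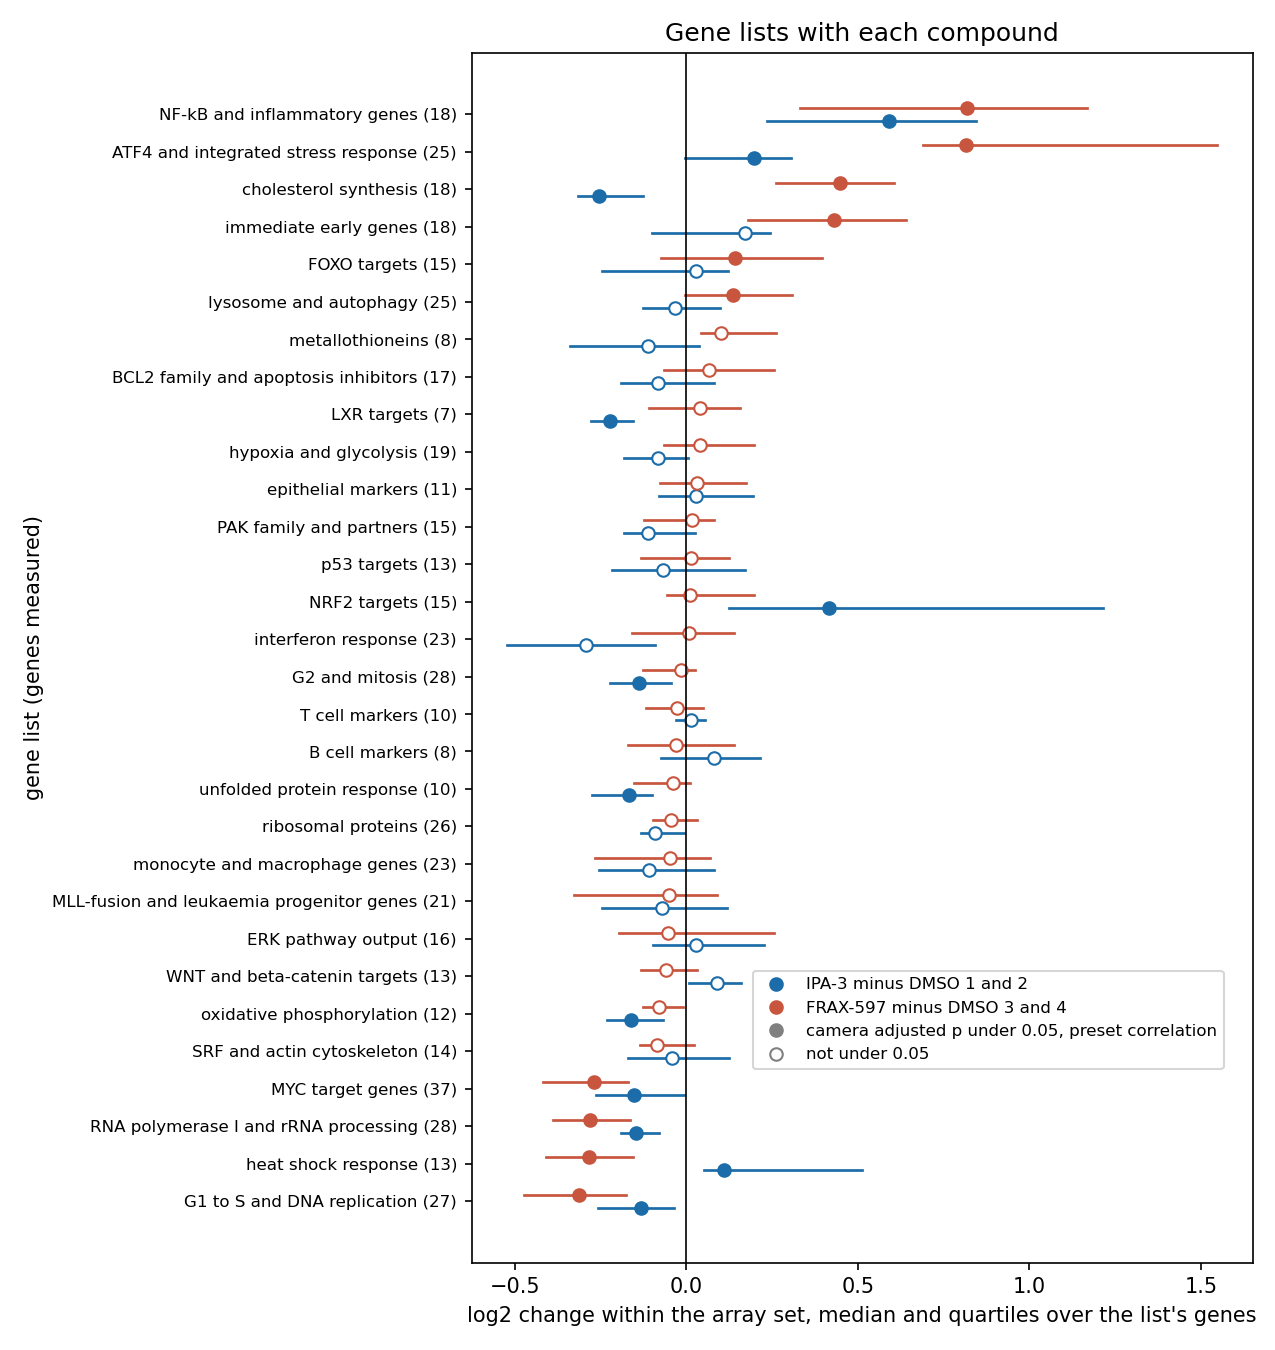
Median (point) and quartiles (line) of the within-set log2 change over the measured genes of each of 30 lists, for IPA-3 and FRAX-597, filled where the camera adjusted p is under 0.05 at the preset correlation of 0.01. The ATF4 list lies at 0.20 with IPA-3 and 0.82 with FRAX-597, NRF2 targets at 0.42 and 0.01, and cholesterol synthesis at -0.25 and 0.45. None of the calls held with an estimated correlation in these fits.

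MYC itself (probe 17072669) was lower with FRAX-597 in both arrays. Its level was 8.51 ± 0.0045 in the DMSO arrays of that set and 7.64 ± 0.30 with FRAX-597 (SD, n = 2 each), 0.549 of the control level (log2 change -0.87, SE 0.15). This did not pass adjustment over all genes in limma (adjusted p = 0.132 within the set, 0.235 with pooled controls) and did with the pair block (adjusted p = 0.0207) or without FRAX-597 2 (-1.08, adjusted p = 0.0123). The pair block was chosen from these same values, so its call of MYC is no separate support. With IPA-3, MYC was 8.53 ± 0.04 against 8.71 ± 0.01 (SD, n = 2 each), a log2 change of -0.18 (SE 0.15; adjusted p = 0.84). The difference between the within-set changes was -0.68 (SE 0.21; adjusted p = 0.674). Against the 4 pooled DMSO arrays, MYC had a change of -0.97 with FRAX-597 (2-sided exact permutation p = 0.0667, the smallest that the 15 splits allow). With IPA-3 that change was -0.08 (2-sided exact permutation p = 0.4), and 0.17 after quantile normalization. Both permutations exchange arrays across the 2 sets, so their p-values ignore the array set. Among the kinases themselves, PAK2 had changes of 0.05 with IPA-3 and 0.09 with FRAX-597 (SE 0.11), PAK4 of 0.16 and 0.05 (SE 0.14), and PAK5 of -0.19 and 0.14 (SE 0.24), none called. Against the pooled controls PAK2 and PAK4 were at -0.07 and -0.40 with IPA-3, where the median of all genes was -0.26. PAK5 changed sign without DMSO 2 for IPA-3 (0.07), and PAK5 and PAK4 without FRAX-597 1 for FRAX-597 (-0.18 and -0.07). PAK1, PAK3 and PAK6 were not analysed here.

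The compounds were then compared with each other. THBS1 and SYT4 differed in the pooled-control fit and in the within-set fit. THBS1 changed by 4.64 more with FRAX-597 than with IPA-3 (SE 0.31; limma adjusted p = 0.011) and SYT4 by 2.23 more (SE 0.19; adjusted p = 0.0372). The count was 0 without IPA-3 1, IPA-3 2, DMSO 1 or DMSO 2 (508 to 936 at an unadjusted p under 0.05), 4 without DMSO 4, 12 without FRAX-597 1 and 27 without FRAX-597 2, and SYT4 lost its call also without DMSO 3 (0.132) or DMSO 4 (0.102). The pair block called 38 genes (26 higher, 12 lower), and an unadjusted p under 0.05 was found for 909 genes in the within-set fit. Because each compound was measured in its own set, FRAX-597 minus IPA-3 without controls gave 7965 genes when only these 4 arrays were fitted.

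By lists, stress and sterol genes differed between the compounds. All 25 ATF4 genes had a higher log2 change with FRAX-597, by a median of 0.75 (camera adjusted p = 5.18e-15, and adjusted p = 0.39 with an estimated correlation; median 0.48 without FRAX-597 1; 7 genes adjusted over the list alone, 0 over all genes). Of 18 cholesterol synthesis genes 17 did so, by a median of 0.65 (camera adjusted p = 7.95e-14, and adjusted p = 0.219 with an estimated correlation; 8 genes adjusted over the list alone, 0 over all genes), MSMO1 by 1.59 (SE 0.28). All 13 heat shock genes were lower with FRAX-597 than with IPA-3 relative to their controls, by a median of -0.48 (camera adjusted p = 2.51e-08, and adjusted p = 0.219 with an estimated correlation; median -0.30 without DMSO 3; 5 genes adjusted over the list alone, 0 over all genes). NRF2 targets were lower in 13 of 15 cases, by a median of -0.41 (camera adjusted p = 4.44e-09, and adjusted p = 0.219 with an estimated correlation; 5 genes adjusted over the list alone, 0 over all genes), SRXN1 by -1.65 (SE 0.20). Among 37 MYC targets 25 were lower with FRAX-597, by a median of -0.12 (camera adjusted p = 0.00248, and adjusted p = 0.468 with an estimated correlation). Adjusted over the list alone 2 were lower, and the call was lost without IPA-3 1 (median -0.05, 0.0779) or FRAX-597 2 (median 0.0004, 0.145). The RNA polymerase I and rRNA processing list had a median of -0.15 (camera adjusted p = 0.00676, and adjusted p = 0.686 with an estimated correlation) and lost its call without the same arrays (0.0779 and 0.616), with a median of -0.0163 without FRAX-597 2. In total 11 of 30 lists differed, 6 higher and 5 lower, 5 of them with camera adjusted p of 0.0287 or 0.047 and no stable call when arrays were left out. The other 19 had camera adjusted p from 0.0591 to 0.972. The compounds were given at different doses by mass, each at a single dose.

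Few genes could be called for both compounds. In the within-set fit 0 genes passed for both, 60 had an unadjusted p under 0.05 and were higher with both, and 77 were lower with both. Independent lists would share 18.7 and 22.1, and simulated unchanged groups shared 30.3 and 30.6 on average over 100 draws. Opposite directions were seen for 13 and 25 genes, where independent lists would give 16.7 and 24.7 and simulated unchanged groups gave 30.5 and 31.3. The pair block gave 13 genes called for both, and leaving out FRAX-597 1 or FRAX-597 2 gave 2 or 11. Across 14884 genes, which are not independent replicates, the within-set changes correlated at r = 0.19 (rho = 0.11, covariance 0.0101). Simulated unchanged groups gave a mean r of 0.00188 and covariance of 8.79e-05 over 100 draws. With no shared controls, a mean near 0 was fixed in advance. No spread over the draws is given, so whether noise in these arrays could give 0.19 was not tested. The observed r was 0.0568 without FRAX-597 1, 0.139 without DMSO 4 and 0.0871 with every probe. With pooled controls r was -0.42 (covariance -0.0459), where unchanged groups gave -0.55 (covariance -0.0558). MYB had changes of -0.87 with IPA-3 (SE 0.11; adjusted p = 0.0941) and -0.93 with FRAX-597. CYSLTR1 had -0.97 with FRAX-597 (SE 0.14; adjusted p = 0.0695) beside its fall with IPA-3, and RXFP1 had -0.76 with IPA-3 (SE 0.11; adjusted p = 0.182) beside its fall with FRAX-597. IL7R had 1.33 with IPA-3 (SE 0.25; adjusted p = 0.29) beside its rise with FRAX-597.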

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

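Of the tests in this part, all 3 on the DMSO arrays, both on NRF2 genes in the DMSO arrays, and the differences between within-set changes were chosen only after the result was seen.

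DMSO 3 and 4 lay apart from DMSO 1 and 2 in 8918 of 14884 genes in limma. The other 2 pairings mix the sets, which widens their spread, so their 0 genes in limma are no separate evidence. One offset per array cannot be the whole cause, since 4501 genes still differed after median centring. A different distribution of values in the 2 sets cannot be either, since 4093 still differed after quantile normalization. After that normalization 26% of the dimmest genes, the lowest 4961 by mean, differed and 28.25% of the others, which is consistent with a probe-specific technical batch, although a difference between cultures stays open. No biological explanation was tested, because the labels describe the 4 DMSO arrays alike.

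NRF2 targets ranked higher with IPA-3 (median 0.42, 13 of 15 above 0), a camera call lost with an estimated correlation (adjusted p = 0.328). They were not called with FRAX-597, with a median difference of -0.41 between the compounds (camera adjusted p = 4.44e-09, and adjusted p = 0.219 with an estimated correlation). One array cannot be the cause, since the highest camera adjusted p with any array left out was 1.81e-07. Raised NRF2 genes in DMSO 3 and 4, as a reason for the missing call with FRAX-597, cannot be told apart, since members went both ways there (median -0.24 relative to all genes, SD 0.667) and SRXN1 and OSGIN1 were higher, by 0.60 and 0.39. The change with IPA-3 was measured against DMSO arrays of its own set, whereas array set and dose are confounded with the difference between the compounds.

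With FRAX-597 the ATF4 and integrated stress response list lay higher and MYC targets lower. Both calls were lost with an estimated correlation (camera adjusted p = 0.191 for each). In FRAX-597 1 minus DMSO 3 and in FRAX-597 2 minus DMSO 4, at least 24 of 25 ATF4 genes were higher. Of 37 MYC targets 33 were lower in one difference and 36 in the other, so neither list rests on one pair of arrays. The ATF4 list also changed more than with IPA-3 (median difference 0.75, camera adjusted p = 5.18e-15, and adjusted p = 0.39 with an estimated correlation), and MYC targets differed by -0.12 (0.00248, adjusted p = 0.468 with an estimated correlation, lost without IPA-3 1 at 0.0779 or FRAX-597 2 at 0.145, where the median was 0.0004). An effect of FRAX-597 on both lists may account for this, as a hypothesis found and tested on the same arrays at a single dose.

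Other lists also differed between the compounds with camera at the preset correlation, and all 8 of these calls were lost with an estimated correlation. Cholesterol synthesis changed by a median of 0.65 more with FRAX-597 (camera adjusted p = 7.95e-14, and adjusted p = 0.219 with an estimated correlation). Heat shock genes had a median difference of -0.48 (2.51e-08, and adjusted p = 0.219 with an estimated correlation). RNA polymerase I and rRNA processing had -0.15 (0.00676, and adjusted p = 0.686 with an estimated correlation), lost without IPA-3 1 (0.0779) or FRAX-597 2 (0.616, median -0.0163). The unfolded protein response list had 0.18 (0.0287, and adjusted p = 0.392 with an estimated correlation), with a highest adjusted p of 0.11 when 1 array was left out and calls without DMSO 2, IPA-3 1 and FRAX-597 2 only. Immediate early genes had 0.28 (0.0287, and adjusted p = 0.724 with an estimated correlation) and went to 0.18 without DMSO 4 and -0.14 without FRAX-597 1. G1 to S and DNA replication had -0.13 (0.0287, and adjusted p = 0.724 with an estimated correlation), lost without DMSO 1, DMSO 3, IPA-3 1 or FRAX-597 1 (0.0583 to 0.637), with a median of -0.07 without FRAX-597 1. Mitotic genes had 0.12 (0.047, and adjusted p = 0.724 with an estimated correlation), called without DMSO 3 and FRAX-597 1 only, with adjusted p up to 0.616 and medians of 0.0451 without DMSO 4 and 0.0411 without FRAX-597 2. With pooled controls this list and the unfolded protein response list ranked lower in the same difference, with medians of 0.53 and 0.24. FOXO targets had 0.15 (0.0287, and adjusted p = 0.409 with an estimated correlation), lost without DMSO 1, DMSO 4, IPA-3 2 or FRAX-597 1 (0.0562 to 0.267), with a median of 0.09 without DMSO 4 and 0.004 without FRAX-597 1. Of single genes, THBS1 changed by 4.64 more with FRAX-597 and SYT4 by 2.23 more.

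Among the 4 DMSO arrays, 3 of 90 genes checked had an array set apart by a large gap relative to the range. They were MSMO1, highest in DMSO 3 (gap over range 0.896), NAT10, highest in DMSO 4 (0.978), and RELB, highest in DMSO 3 (0.867). For NAT10 the gap itself was small, 9.40 in DMSO 4 against 9.27 in each of the others. Chance gives about 5% for 4 arrays drawn alike. These arrays form 2 pairs shifted against each other, so that rate is no benchmark here. Outside the named genes, 4 of 37519 probes without a gene name were called for FRAX-597 within its set, all higher.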

How the results depend on the processing

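The pair block, the difference of within-set changes, and median centring of the DMSO split were chosen only after the result was seen, while the other alternatives were fixed before the data were examined. Leaving out an array leaves some groups with 1 array, which is then assumed to vary like the others. Robust spread was not run for the list tests. Of the main results under all alternatives 214 stayed the same, 97 moved, 9 reversed and 2 passed the threshold newly. A count was taken as the same while it stayed within a fixed factor of its reference. The 12 lists for IPA-3 within its set that became 8 with quantile normalization were thus the same. Some main results were counts of 0 that stayed 0, such as the genes for IPA-3 with pooled controls. The 214 therefore does not measure how stable the main results were. Of single genes in the within-set fit 1855 stayed the same, 136 lost their call, 45 gained one and 12 reversed, and of single lists 438, 137, 0 and 8. Most of these single genes were not called to begin with and could not lose a call. The 1855 therefore does not measure how stable the calls were. Among called genes with FRAX-597, URB2 lost its call in 10 of 17 settings, MYB in 9 of 17 and THBS1 in 1 of 17. Where no cause is named below, the cause was not tested. The NRF2, heat shock and NF-kB lists for IPA-3, and the ATF4, cholesterol, MYC target, G1 to S, RNA polymerase I and heat shock lists for FRAX-597, kept their direction and call in all 16 settings other than the list test itself. All of these calls were lost in camera with an estimated correlation. With fry all but the NRF2 list were lost. The processed table gives no background values, so leaving out the 4961 dimmest genes stands in for a limit on signal.

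With the fit of pooled controls as the reference, IPA-3 changed 0 genes (limma, 843 at an unadjusted p under 0.05) and 4 lists, FRAX-597 changed 5 genes and 11 lists, and the compounds differed in 2 genes and 8 lists. With DMSO 1 and 2 as the only controls, IPA-3 changed 5 genes and 12 lists, FRAX-597 changed 8991 genes, MYC with FRAX-597 was at -1.07 and passed (0.00107), and 4 genes changed with both compounds. With DMSO 3 and 4 as the only controls, IPA-3 changed 9139 genes and 7 lists, FRAX-597 changed 23 genes, MYC with IPA-3 was at 0.0201, and 6 genes changed with both. By construction, the 8991 and 9139 compare arrays of different sets. The pair block gave 72 genes and 13 lists for IPA-3, 202 genes for FRAX-597, 38 genes and 13 lists between the compounds, 13 genes for both, and a call for MYC with FRAX-597 at -0.87 (0.0207). Quantile normalization gave 26 genes for FRAX-597, 12 between the compounds, and 0.17 for MYC with IPA-3. Median centring gave 22, 11 and 0.16. Both remove the offset between the sets. Without the dimmest genes FRAX-597 changed 8 genes and the compounds differed in 1, and the intensity trend gave 8 for FRAX-597. With only the groups compared in the fit, FRAX-597 changed 2 genes and the compounds differed in 7965. With an estimated correlation 2 lists were called for IPA-3, 0 for FRAX-597 and 1 between the compounds, and fry gave 0, 2 and 3. Leaving out 1 array gave 3 to 7 lists for IPA-3 (7 without DMSO 4), 2 to 11 genes for FRAX-597 (11 without DMSO 4), and 0 to 7 genes between the compounds (0 without IPA-3 1 or IPA-3 2, 7 without DMSO 3).

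In the within-set fit IPA-3 changed 5 genes, FRAX-597 changed 23 and the compounds differed in 2. With every probe as its own feature the counts were 0 for IPA-3 and 6 for FRAX-597, with more features tested by construction. Of those 6 probes, 4 carried no gene name. With the probes of each gene averaged, 7 lists differed between the compounds. For IPA-3 quantile normalization gave 3 genes and the intensity trend 8, which also gave 1 gene for both compounds. With only the groups compared IPA-3 changed 96 genes and FRAX-597 changed 0. Those fits take the spread from 1 set, whereas the within-set fit takes it from both. Pooled controls gave 0 genes and 4 lists for IPA-3 and 5 genes for FRAX-597. The pair block gave 72, 202 and 38 genes, and 13 for both. Without the dimmest genes the compounds differed in 1 gene. With an estimated correlation 0 lists were called for IPA-3, 0 for FRAX-597 and 0 between the compounds. The test with fry gave 1 list for IPA-3, the NRF2 targets, and 0 and 0 for the others. Leaving out 1 array gave 0 to 24 genes for IPA-3, 2 to 227 for FRAX-597 (227 without FRAX-597 2), 0 to 27 between the compounds, 0 to 11 for both (11 without FRAX-597 2), and 6 to 15 lists between the compounds.

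Reversals with pooled controls, whose IPA-3 changes had a median of -0.26 over all genes, were these for IPA-3: RNA polymerase I and rRNA processing, ranked higher at a median of -0.0928, and the unfolded protein response, ranked higher at -0.24. Of single genes, PAK2 was at -0.0698, PAK4 at -0.40, PTGS2 at -0.45, SDF2L1 at 0.41, VEGFA at -0.24 and WDR3 at 0.0749. Between the compounds, where that median was 0.49, the unfolded protein response (0.24) and mitosis (0.53) ranked lower, SEL1L was at -0.24 and TXNIP at -0.0806. Leaving out 1 array, PAK5 with IPA-3 ran from -0.44 to 0.0680 (without DMSO 2). With FRAX-597, PAK4 ran from -0.0660 to 0.17, PAK5 from -0.18 to 0.46, the NF-kB list from -0.0422 to 1.81, and the lysosome list from -0.0437 to 0.29, each lowest without FRAX-597 1. Immediate early genes between the compounds ran from -0.14 (without FRAX-597 1) to 0.69. The lysosome list was at -0.0096 without DMSO 4.

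The correlation of the compounds' within-set changes was 0.19. It was 0.255 without the dimmest genes, 0.0871 with every probe, and 0.0568 to 0.219 with an array left out (0.0568 without FRAX-597 1). It turned to -0.424 with pooled controls. By construction, that setting and the next 5 set at least one compound against DMSO arrays of the other set. With IPA-3 against DMSO 3 and 4 and FRAX-597 against DMSO 1 and 2 it was -0.791. With DMSO 1 and 3 for IPA-3 it was -0.451, with DMSO 2 and 4 -0.487, with DMSO 1 and 4 -0.480, and with DMSO 2 and 3 -0.459, the other pair serving FRAX-597. The 8918 genes between DMSO 1 and 2 and the others were 4093 after quantile normalization, 4501 after median centring and 5551 without the dimmest genes, the last with fewer genes tested.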

Other observations

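All tests in this part were chosen after the data had been examined.

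Interferon and inflammatory genes differed inside the second set, between DMSO 4 with FRAX-597 2 and DMSO 3 with FRAX-597 1. In this contrast 1704 of 14884 genes differed at a limma adjusted p under 0.05, 664 higher and 1040 lower. All 23 interferon response genes were lower than the median gene in DMSO 4 and FRAX-597 2, by a median of -1.47 (camera adjusted p = 2.73e-24, and adjusted p = 0.294 with an estimated correlation). NF-kB and inflammatory genes had a median of -1.12 relative to all genes (camera adjusted p = 3.86e-09, and adjusted p = 0.381 with an estimated correlation). The ATF4 and integrated stress response list had -0.47 (camera adjusted p = 2.84e-06, and adjusted p = 0.381 with an estimated correlation), and immediate early genes had -0.36 (camera adjusted p = 1.79e-05, and adjusted p = 0.381 with an estimated correlation). Monocyte and macrophage genes had -0.57 (camera adjusted p = 4.42e-06, and adjusted p = 0.294 with an estimated correlation). Lysosome and autophagy genes had -0.35 (camera adjusted p = 1.32e-06, and adjusted p = 0.294 with an estimated correlation). Hypoxia and glycolysis genes had -0.24 (camera adjusted p = 0.00159, and adjusted p = 0.294 with an estimated correlation), and ERK pathway output had -0.31 (camera adjusted p = 0.00892, and adjusted p = 0.381 with an estimated correlation). RNA polymerase I and rRNA processing had -0.15 (camera adjusted p = 0.0394, and adjusted p = 0.688 with an estimated correlation), and WNT targets had -0.20 (camera adjusted p = 0.0402, and adjusted p = 0.381 with an estimated correlation). The labels name no factor that pairs these arrays.

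In DMSO 3 and 4 against DMSO 1 and 2, ribosomal protein genes ranked lower than other genes, with a median of -0.42 relative to all genes (camera adjusted p = 0.00119, and adjusted p = 0.717 with an estimated correlation). Neither this nor the rankings that follow were tested apart from the difference in scale between the sets. Heat shock genes had -0.45 (camera adjusted p = 0.0299, and adjusted p = 0.717 with an estimated correlation). Metallothioneins had -0.66 (camera adjusted p = 0.0436, and adjusted p = 0.717 with an estimated correlation), and monocyte and macrophage genes -0.31 (camera adjusted p = 0.0497, and adjusted p = 0.88 with an estimated correlation). Interferon response genes had the largest median, 0.92 with 21 of 23 above the median gene. The test differed from it in sign, ranking them lower, and did not call them (camera adjusted p = 0.973).

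Among genes with an unadjusted p under 0.05 for both compounds, some were chosen for mention after their values were seen. CCR2, a chemokine receptor of monocytes, had log2 changes of -1.39 with IPA-3 and -1.52 with FRAX-597. EGR1, an immediate early transcription factor, had -0.96 and -0.70. HIVEP1 had 1.20 with IPA-3 and rose by 1.69 with FRAX-597 (limma adjusted p = 0.0306). None of these passed the adjusted threshold for IPA-3, and CCR2 (limma adjusted p = 0.279) and EGR1 (0.241) did not for FRAX-597.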
